A study of Homo sapiens with 6 samples.

How the data were processed

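RNA was measured on 6 arrays, 3 of untreated MDA-MB-231 cells and 3 of MDA-MB-231 cells cocultured for 3 h with tumour-associated macrophages (TAMs) in a transwell, where a porous membrane parts the cells. MDA-MB-231 is a human breast cancer cell line, here grown in DMEM with 10% FBS. The arrays carry probes for mRNA and long non-coding RNA and were hybridised in 1 colour with Cy3-labelled cRNA. The labels describe the extracted RNA once as RNA of macrophages, while the sample titles and cell type say breast cancer cells, and the samples are treated here as breast cancer cells.

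The scanner files hold spot intensity made with Agilent Feature Extraction 12.0.3.1, per the file headers, after background subtraction and detrending within the array and with no normalization between arrays. The same files hold marks of 0 or 1 for each spot, such as well above background, saturated or outlier, and other settings per the file headers. The series matrix holds log2 values deposited by the authors, 1 per probe and array. Their normalization is not stated. The columns had medians of 3.54 to 3.57 and nearly equal quantiles, correlated with the log2 scanner signal of their own array at 0.998 to 0.999 across probes, and rose with it with slopes of 0.911 to 0.929. The scale and centring of the series matrix thus differ from those used here, its base is taken as log2 from the slope, and its direction was the same for 99.9% of the 14833 features past the threshold.

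Intensities were log2-transformed and shifted so that the 75th percentile of non-control probes was 0 on each array. Outlier spots were left out, which were 19 to 40 per array, and the spots of a probe were averaged. Of 120864 non-control probes, 41172 (34.1%) had 1 gene symbol, matched by Entrez gene ID, and 79692 had none. The 23879 symbols comprised 17833 protein-coding genes, 5201 non-coding genes and 845 pseudogenes. A gene was represented by its probe with the highest mean signal over the 6 arrays, whatever the group, and a probe without a symbol stood for itself. A feature was tested where its spots were well above background on every array of at least 1 group, which left 55132 features. No coordinates are given, because the array annotation and the gene table name different genome builds and no genome was at hand.

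Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the package data.table (version 1.17.8). The Benjamini-Hochberg adjustment ran over all tested features, and the threshold was an adjusted p of 0.05, two-sided. Fold changes are TAM coculture over untreated, with the moderated standard error (SE). An exact test on 3 against 3 arrays cannot go below 0.1, so single-gene exact tests were not used. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 26 lists with at least 3 tested members, and again with an estimated correlation and with fry. Fry's directional p asks whether the genes of a list move one way on balance, and its mixed p whether they change in either direction. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

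The grouping, the tests, the gene lists, the marker lists and the rule for named genes were fixed before the data were examined. The rule took the 10 protein-coding and the 5 non-coding genes with the largest rise and the largest fall among those past the threshold, above background on all 6 arrays and with no overlap between groups. It also took the 3 brightest genes each way that were above background in 1 group only, the 3 members of each list with the smallest p, and HIF1A, EGLN1, SLC2A1, HK2, LDHA, PDK1, VEGFA and HISLA (LINC01146) whatever their values. A gene above background on all arrays of 1 group and none of the other is given as a bound, computed against the lowest well-above-background signal on the dim arrays. That signal is the lowest of any probe and not a limit of the gene's own probe. The bound is therefore approximate and holds under the main processing only.

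The method was tested on simulated data with the spread and group sizes of these arrays. It recovered 25.4% of the 67 planted log2 changes of 0.5, 83.6% of the 67 planted changes of 1 and 98.5% of the 66 planted changes of 2. Of 147 calls 9 were unchanged features (6.12%), and 0 of 25 unchanged lists were called by camera. The simulated genes varied independently, so this does not test camera on genes that vary together. The simulation gave 147 calls against 14833 in these arrays, so the recovered shares need not hold here.

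The arrays sat on 2 slides, scanned on 1 day: untreated replicates 1 and 2 on slide 1, and untreated replicate 3 with all coculture replicates on slide 2. Slide was therefore also fitted as a block. The 4 arrays of slide 2 were also fitted alone, with the lone untreated array assumed to vary like the others. Both arrays of slide 1 are untreated, so the fold changes of these 2 fits are the same and rest on 1 untreated array. The fits differ only in the estimate of spread and are not separate checks. Both groups carry the replicate numbers 1 to 3. The design states no pairing and the cells are 1 line, so the arrays were compared unpaired, with the replicate number as a block among the alternatives. Other alternatives were quantile normalization, background correction by normexp with an offset of 50, a median shift, the series matrix values, other filters on dim probes, other ways to combine probes, other eBayes settings, a fold limit of 2, outlier spots kept, and each array left out in turn. A random slide effect, a fit within slide 2, a shift by the 6 E1A spike-in probes and protein-coding genes as list background were chosen after the data were seen.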

Results

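The data set holds 6 arrays in 2 groups of 3, untreated MDA-MB-231 breast cancer cells and the same line after 3 h of transwell coculture with TAMs. On each array 55.0% to 57.2% of non-control spots were well above background, none was saturated, and the 75th percentile of signal lay between 97.4 and 104 intensity units. Across features, arrays of the same group correlated at 0.996 to 0.997 and arrays of different groups at 0.986 to 0.988. The first principal component held 71.0% of the variance and parted the groups. The second held 9.92% and set untreated replicate 3, which shares slide 2 with the coculture arrays, at 38.9. The other untreated arrays, on slide 1, lay at -12.7 and -23.7, and the coculture arrays at 6.52, 3.98 and -12.9. The second component thus set untreated replicate 3 apart and did not fully part the slides. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, and the number of arrays limits the precision.

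The comparison asks how coculture with TAMs changes the mRNA and lncRNA of breast cancer cells. The other group is labelled only as untreated, so effects of the TAMs cannot be told apart from those of the coculture setup. After coculture, 17 of 21 target genes of NF-kB, the transcription factor of inflammatory signalling, were higher, among them inhibitors of the pathway, with NFKBIA 8.84-fold (log2 change 3.14 ± 0.07 SE, adjusted p = 2.35e-05, n = 3 per group) and TNFAIP3 5.59-fold above untreated cells. With them rose 11 of 15 cytokine and chemokine genes and 20 of 23 genes known to be induced by low oxygen, such as ANGPTL4 at 3.57-fold and VEGFA, the vascular growth factor, at 2.33-fold. None of these lists passed with an estimated correlation (adjusted p = 0.295, 0.323 and 0.372), nor did any other list. With 6 arrays that test has little power. The largest rise among named non-coding genes was 21.7-fold for MIR210HG, the host transcript of a hypoxia-induced microRNA. The mRNA of HIF1A itself, which encodes the oxygen-regulated subunit of the hypoxia factor, read 0.11 ± 0.06 on the log2 scale and did not pass (adjusted p = 0.218).

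In all, 7650 of 55132 tested features were higher and 7183 lower, of which 664 and 1691 changed at least 2-fold. Among protein-coding genes 2201 of 13667 were higher and 1708 lower. The groups did not overlap for 24891 features (45.1%), against a share of 10% by chance. The median log2 change of all features was 0.03. It was -0.08 in the dimmest 10% of features, where 459 were higher and 1150 lower, and 0.12 in the brightest 10%, where 1094 were higher and 72 lower. The balance of directions depended on scaling: 51.6% of called features were higher here, 72.2% after a median shift and 38.0% after a shift by spike-in probes, with a median of all features of 0.13 and -0.03. With slide as a block, where the contrast rests on 1 untreated array, 4170 features were higher and 4598 lower.

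**Figure D1:**
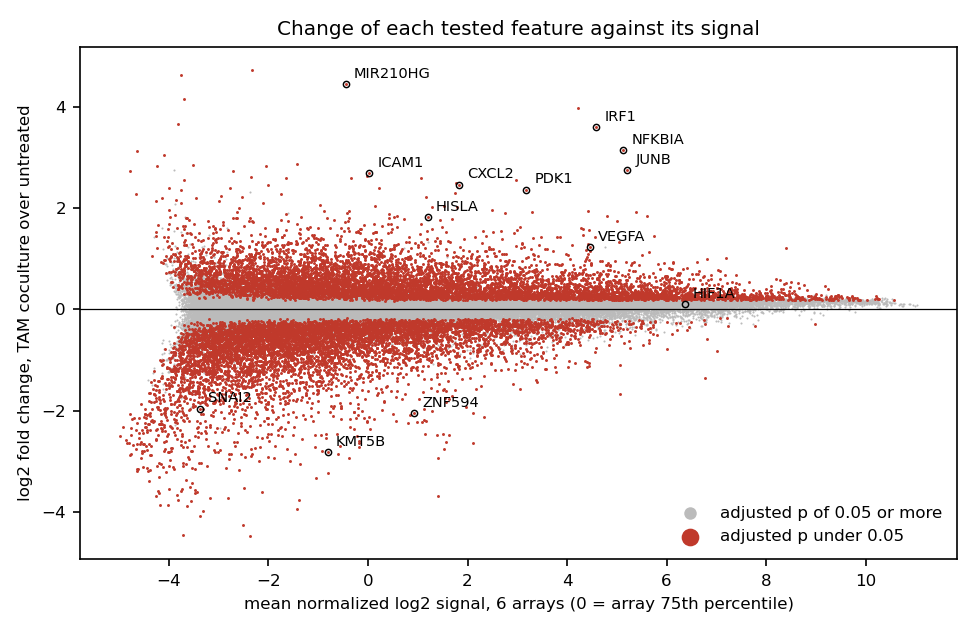
Log2 fold change of each tested feature (TAM coculture over untreated, vertical axis) against its mean normalized log2 signal over 6 arrays (horizontal axis, 0 at the 75th percentile of each array). Red points passed an adjusted p of 0.05, and labelled circles mark named genes from MIR210HG at 4.44 to KMT5B at -2.82.

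Of 21 tested NF-kB targets, 17 rose and 0 fell (17 adjusted over the list alone), and 4 did not pass. The list median was 1.06, and 1.10 with slide as a block, with camera adjusted p = 8.22e-11, and adjusted p = 0.295 with an estimated correlation. Besides NFKBIA and TNFAIP3, both feedback inhibitors of the pathway, CD83, a surface protein of activated immune cells, rose by 1.93 ± 0.06. IRF1, an interferon-regulatory transcription factor, rose 12.1-fold (3.60 ± 0.42, adjusted p = 0.00144), and ICAM1, a leukocyte adhesion protein, 6.47-fold (2.69 ± 0.41, adjusted p = 0.00414). Both varied more between coculture arrays than most named genes (SD 0.90 and 0.87), and within slide 2 their adjusted p rose to 0.0582 and 0.0864.

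Of 15 tested cytokine and chemokine genes, 11 rose and 1 fell (14 adjusted over the list alone). The median was 1.02, or 0.97 with TNF, CXCL1 and CCL20, which were dim in untreated cells, set at their bound, and 1.01 with slide as a block. Tested with camera, the list had adjusted p = 1.75e-05, and adjusted p = 0.323 with an estimated correlation. CXCL2 and CXCL3, which attract neutrophils, rose by 2.46 ± 0.14 and 1.80 ± 0.07, and CSF1, the growth factor of macrophages, by 1.33 ± 0.08. CCL20, a lymphocyte attractant, was at least 2.33-fold higher under the main processing. The member that fell was IL11, at -0.63 ± 0.05, named after its value was seen.

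Of 23 tested hypoxia-inducible genes outside glycolysis, 20 rose and 0 fell (20 adjusted over the list alone), with a median of 0.60, and 0.64 with slide as a block. The camera test had adjusted p = 4.05e-10, and adjusted p = 0.372 with an estimated correlation. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 1.84 ± 0.07, KDM3A, a histone demethylase, by 1.60 ± 0.07, and VEGFA by 1.22 ± 0.07. The 3 members that did not pass, CITED2, STC2 and DDIT4, read -0.14, -0.03 and 0.02, and were named after their values were seen.

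Glycolysis genes moved the same way: 14 of 20 rose and 0 fell (15 adjusted over the list alone), with a median of 0.40, and 0.37 with slide as a block. Camera gave adjusted p = 5.55e-08, and adjusted p = 0.372 with an estimated correlation. PDK1, which inhibits pyruvate dehydrogenase, rose 5.14-fold (2.36 ± 0.08, its 3 probes between 0.40 and 2.36), PFKFB4, a regulator of phosphofructokinase, by 1.09 ± 0.06, and ENO2, an enolase, by 0.90 ± 0.06. HK2, a hexokinase, rose by 1.00 ± 0.08, though another of its 3 probes read -0.001. SLC2A1, the glucose transporter, and LDHA, lactate dehydrogenase, rose by 0.47 ± 0.06 and 0.40 ± 0.06. Within slide 2 their adjusted p were 0.0530 and 0.0705.

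Among 11 tested HIF regulators 5 rose and 0 fell (5 adjusted over the list alone), with a median of 0.13, and 0.14 with slide as a block. Tested with camera, the list had adjusted p = 0.00737, and adjusted p = 0.446 with an estimated correlation. Quantile normalization ended the call at 0.0785, with a median of 0.07. EGLN3 and EGLN1, prolyl hydroxylases that mark HIF for destruction and also count among the hypoxia-inducible genes, rose by 1.23 ± 0.07 and 0.95 ± 0.06. VHL, the ubiquitin ligase subunit that binds marked HIF, rose by 0.37 ± 0.06, with its 3 probes between 0.07 and 0.37, and adjusted p = 0.0772 within slide 2.

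**Figure D2:**
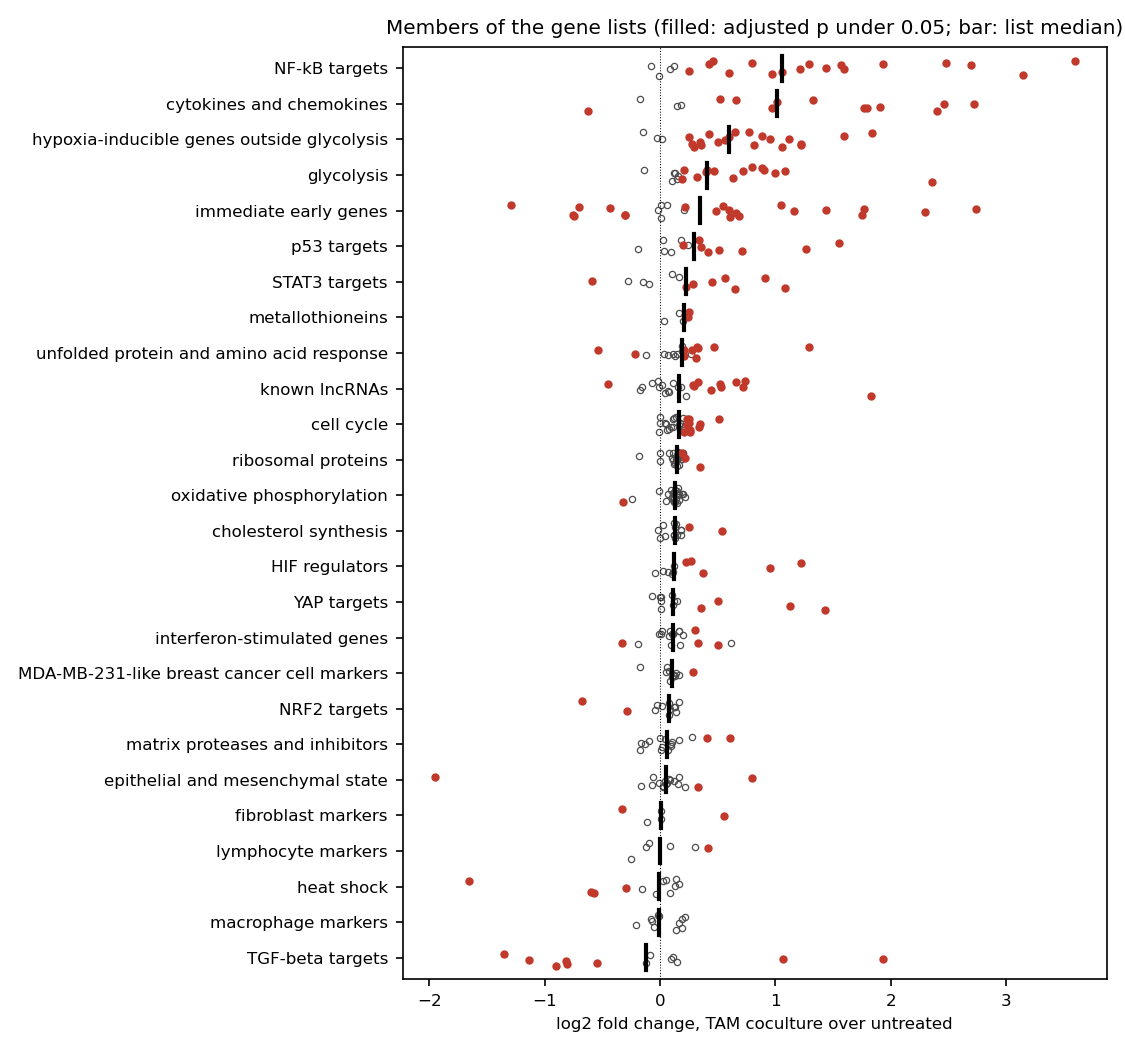
Log2 fold change (TAM coculture over untreated, horizontal axis) of each tested member of the 26 gene lists (vertical axis), filled where the adjusted p was under 0.05, with a bar at the list median. NF-kB targets and cytokines have the highest medians, 1.06 and 1.02, and TGF-beta targets the lowest, -0.12.

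Immediate early genes, the first genes transcribed after a stimulus, went both ways: 14 of 26 rose and 7 fell (22 adjusted over the list alone), with a median of 0.35, and 0.34 with slide as a block. The camera test had adjusted p = 0.0195, and adjusted p = 0.372 with an estimated correlation. At the preset correlation 5 alternatives ended the call, with adjusted p up to 0.0874. Among them were quantile normalization (0.0785) and a median shift (0.0750). JUNB and EGR1, transcription factors, rose by 2.74 ± 0.08 and 2.30 ± 0.12, and KLF10 by 1.44 ± 0.05. JUN read -0.74 ± 0.06 and the MAP kinase phosphatases DUSP1 and DUSP4 -0.70 ± 0.07 and -0.76 ± 0.05, all past the threshold and named after their values were seen.

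Of 14 tested p53 targets 8 rose and 0 fell (11 adjusted over the list alone), with a median of 0.29, and 0.25 with slide as a block. Camera gave adjusted p = 0.000783, and adjusted p = 0.446 with an estimated correlation. BBC3, a pro-apoptotic protein, rose by 1.55 ± 0.08, GADD45A, a stress-induced growth arrest protein, by 1.27 ± 0.07, and GDF15, a secreted stress factor, by 0.71 ± 0.07.

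Among TGF-beta targets 6 of 13 fell and 2 rose (8 adjusted over the list alone), and the list did not pass (median -0.12, or -0.18 with slide as a block, adjusted p = 0.0800). ID1, an inhibitor of differentiation, fell by 1.35 ± 0.07 and SMAD6, an inhibitor of BMP signalling, fell by 1.13 ± 0.07, while BHLHE40, a transcription factor also known from hypoxia, rose by 1.94 ± 0.06. Of 12 heat shock genes 4 fell and 0 rose (4 adjusted over the list alone), with a list median of -0.01, or -0.05 with slide as a block, and adjusted p = 0.198. HSPA1B, an inducible HSP70, fell by 1.66 ± 0.10 and its cochaperone DNAJB1 fell by 0.58 ± 0.07. HSPA1A, nearly identical to HSPA1B in sequence, fell by 0.60 ± 0.11, with adjusted p = 0.102 with slide as a block. Both lists passed downwards under quantile normalization, at adjusted p = 0.0498 and 0.0144, while in the main fit with an estimated correlation they were at 0.372 and 0.596. With every probe counted the TGF-beta median turned to 0.05.

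STAT3 targets stood at the threshold (7 of 13 rose, 1 fell, 10 adjusted over the list alone, median 0.22 in both fits). Camera gave adjusted p = 0.0501, and adjusted p = 0.372 with an estimated correlation. At the preset correlation the call depended on the setting, with adjusted p between 0.000255 (every probe counted) and 0.205 (quantile normalization). PIM1, a survival kinase, rose by 1.08 ± 0.07 and MCL1, an anti-apoptotic protein, by 0.65 ± 0.06. Among YAP targets 4 of 13 rose and 0 fell (4 adjusted over the list alone, median 0.12, or 0.17 with slide as a block), with adjusted p = 0.0307, and adjusted p = 0.372 with an estimated correlation. NUAK2, a kinase, and AMOTL2, a junction protein, rose by 1.43 ± 0.09 and 1.13 ± 0.10. Under quantile normalization the YAP call ended (0.422) and its median was -0.007, and it ended without untreated replicate 3 or coculture replicate 3 (0.0544 and 0.0533). Of 18 interferon-stimulated genes 3 rose and 1 fell (4 adjusted over the list alone, median 0.11, or 0.10 with slide as a block, adjusted p = 0.0800, and 0.0276 with no filter on dim probes). USP18, which restrains interferon signalling, rose by 0.50 ± 0.07, and IRF7 and IFIT3 read 0.33 and 0.30, with adjusted p of 0.0580 and 0.0908 with slide as a block.

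In the unfolded protein and amino acid response 8 of 19 genes rose and 2 fell (12 adjusted over the list alone). The median was 0.19, or 0.14 with slide as a block, where only VLDLR and ATF4 passed. Tested with camera, the list had adjusted p = 0.0170, adjusted p = 0.479 with an estimated correlation and 0.0794 with slide as a block, and 0.205 under quantile normalization. VLDLR, a lipoprotein receptor, rose by 1.29 ± 0.10 and ATF4, the transcription factor of the response, by 0.47 ± 0.07, with adjusted p = 0.0605 within slide 2. CHAC1, which degrades glutathione, fell by 0.54 ± 0.09, with adjusted p = 0.0675 with slide as a block. Of 26 cell cycle genes 10 rose and 0 fell (11 adjusted over the list alone). The median was 0.17, or 0.14 with slide as a block, where only CDC6 and CCNE2 passed. Camera gave adjusted p = 0.000997, and adjusted p = 0.479 with an estimated correlation and 0.315 under quantile normalization. CDC6, a replication licensing factor, rose by 0.52 ± 0.05 and CCNE2, a cyclin, by 0.34 ± 0.05, the latter with adjusted p = 0.0826 within slide 2.

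Another 4 lists passed with medians to be set beside the 0.12 of the brightest 10% of features. Of 26 ribosomal protein genes 3 rose and 0 fell (1 adjusted over the list alone), and none passed with slide as a block. Camera gave adjusted p = 0.00377, and adjusted p = 0.479 with an estimated correlation. Their median was 0.15, or 0.13 with slide as a block. For 25 oxidative phosphorylation genes (0 rose, 1 fell, 0 adjusted over the list alone) it was 0.13, or 0.06 with slide as a block, with adjusted p = 0.0392, and adjusted p = 0.532 with an estimated correlation. Its member that fell, UQCRB of complex III, read -0.32 ± 0.07, against the direction of the list, and no longer passed with slide or replicate number as a block (adjusted p = 0.0688 and 0.0624). Quantile normalization took both medians below 0, to -0.007 and -0.002, and ended all 4 calls. For 16 cholesterol synthesis genes (2 rose, 0 fell, 1 adjusted over the list alone) the median was 0.13, or 0.10 with slide as a block, with adjusted p = 0.0307, and adjusted p = 0.479 with an estimated correlation. For 6 metallothioneins (3 rose, 0 fell, 4 adjusted over the list alone) it was 0.21, or 0.15 with slide as a block. Camera gave adjusted p = 0.0472, and adjusted p = 0.453 with an estimated correlation. The members that rose, MT1E, MT1H and MT1X, no longer passed with slide or replicate number as a block. With slide as a block the calls of oxidative phosphorylation, cholesterol synthesis and metallothioneins ended, at 0.364, 0.120 and 0.169. The metallothionein call also ended with untreated replicate 1, untreated replicate 2, coculture replicate 1 or coculture replicate 2 left out, at 0.0649, 0.0666, 0.0602 and 0.119. The oxidative phosphorylation call ended without untreated replicate 1, coculture replicate 2 or coculture replicate 3, at 0.109, 0.0560 and 0.0940, and the cholesterol synthesis call without untreated replicate 1 or coculture replicate 3, at 0.0649 and 0.0739.

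Genes of the epithelial and mesenchymal state did not pass as a list (2 of 18 rose, 1 fell, 3 adjusted over the list alone, median 0.05, or 0.07 with slide as a block, mean -0.006, adjusted p = 0.278). SNAI1, an EMT transcription factor, rose by 0.80 ± 0.07. SNAI2, its relative, was at least 2.85-fold lower under the main processing, with adjusted p = 0.0594 with slide as a block. Across the alternatives its log2 change shrank to as little as -0.31. The 6 probes of ZEB2 disagreed, between -0.27 and 1.21. Of 16 matrix protease genes 2 rose and 0 fell (2 adjusted over the list alone, median 0.06, or 0.09 with slide as a block, adjusted p = 0.328), with PLAUR, the urokinase receptor, at 0.61 ± 0.06. Of 12 NRF2 targets 0 rose and 2 fell (2 adjusted over the list alone, median 0.08, or 0.05 with slide as a block, mean -0.02, adjusted p = 0.840), with OSGIN1, an oxidative stress response gene, at -0.67 ± 0.08.

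Non-coding genes, which the arrays were chosen to cover, changed in 608 of 2769 cases, 353 higher and 255 lower, and in 376 with slide as a block and 278 within slide 2. Behind MIR210HG (4.44 ± 0.07, its 3 probes between 1.52 and 4.44) the largest rises among those above background on all 6 arrays were DIP2A-IT1 at 1.87 ± 0.06, HISLA at 1.83 ± 0.09, the box C/D small nucleolar RNA SNORD35B at 1.53 ± 0.06 and MIR5087 at 1.50 ± 0.08. HISLA is named for stabilising HIF-1α and rose 3.55-fold (adjusted p = 7.04e-05). The largest falls, under the same limit, were LINC01355 at -2.85 ± 0.07, MIR30C2 at -2.55 ± 0.09, TMCO1-AS1 at -2.14 ± 0.11, ZNF252P-AS1 at -1.74 ± 0.16 and MIR4435-1 at -1.61 ± 0.08. Across the alternatives these falls shrank to as little as -1.56, -0.97, -0.67, -0.51 and -0.61, in that order. The rises, from MIR210HG to MIR5087, shrank to as little as 2.52, 1.33, 1.37, 1.33 and 1.04. Probes of microRNA genes do not tell the mature microRNA from its precursor. Of 24 known lncRNAs 10 rose and 1 fell (12 adjusted over the list alone, median 0.17 in both fits), with adjusted p = 0.00377, adjusted p = 0.295 with an estimated correlation and 0.108 under quantile normalization. MIR22HG, a stress-responsive host transcript, and EPB41L4A-AS1 rose by 0.74 ± 0.07 and 0.66 ± 0.05. The member that fell was HIF1A-AS1, at -0.45, named after its value was seen.

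**Figure D3:**
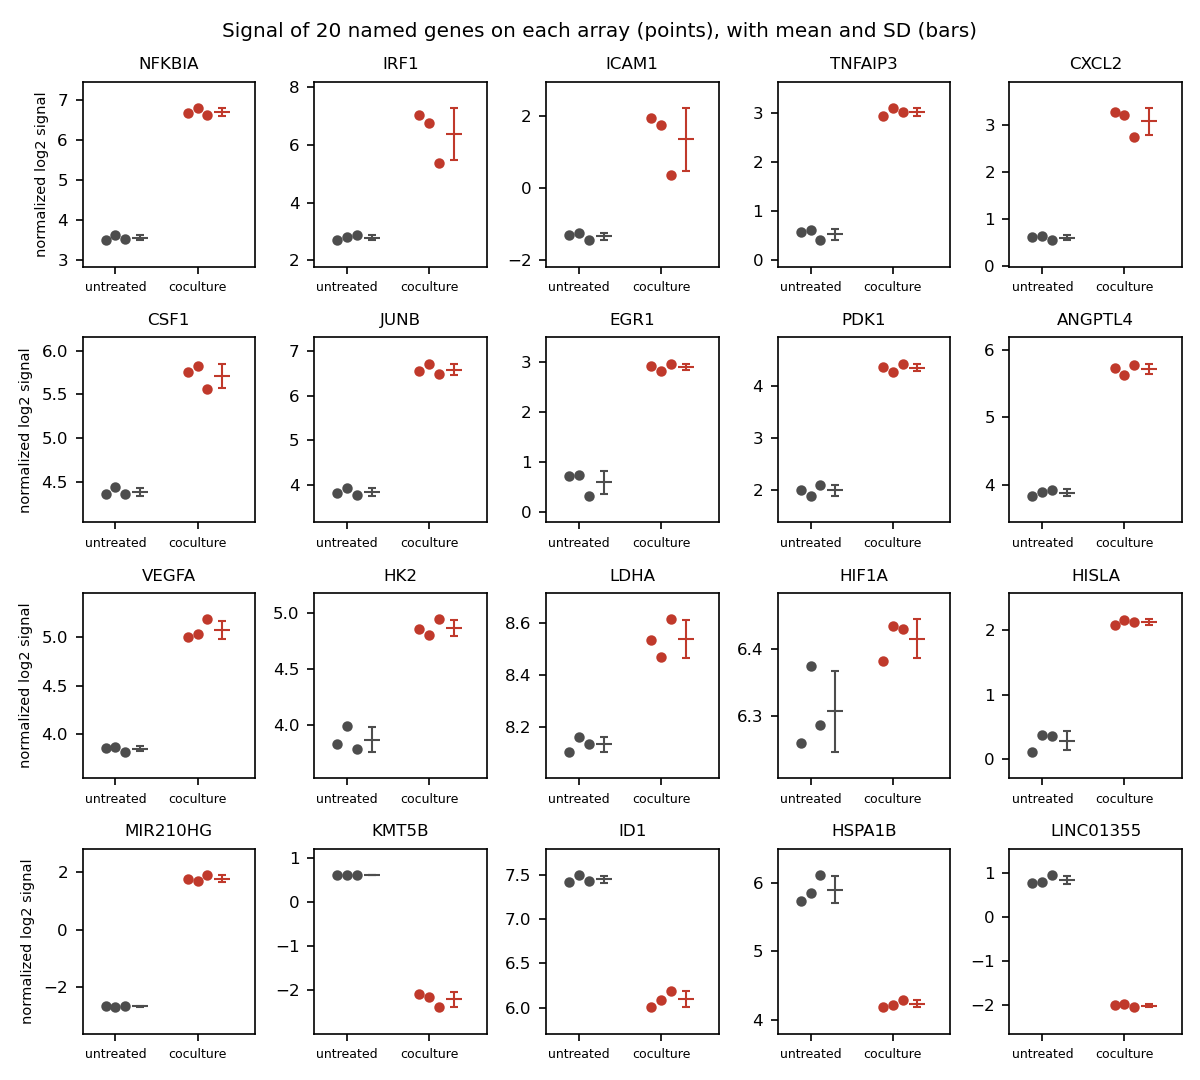
Normalized log2 signal (vertical axis) of 20 named genes on each of the 3 untreated and 3 coculture arrays (points), with the mean and SD beside them. NFKBIA and MIR210HG lie 3.14 and 4.44 higher in coculture, KMT5B and LINC01355 lie at -2.82 and -2.85, and HIF1A differs by 0.11.

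Outside the lists, the largest protein-coding rises among genes above background on all 6 arrays were BCLAF1, a splicing and death-associated factor, at 2.04 ± 0.06 (its probes between 0.27 and 2.04) and PHF13, a chromatin reader, at 2.03 ± 0.11 (between 0.51 and 2.03). The largest falls among such genes were KMT5B, a histone H4 methyltransferase, at -2.82 ± 0.09, ZSWIM3 at -2.46 ± 0.07, TRIM13, a ubiquitin ligase, at -2.36 ± 0.11 and NAPEPLD, which makes N-acylethanolamines, at -2.21 ± 0.11. BLID, ABHD18, GCNA, ZNF594, ZNF616 and PNLDC1 followed, between -2.19 and -1.98. Across the alternatives ABHD18, PNLDC1, GCNA and ZNF616 shrank to as little as -0.59, -0.62, -0.84 and -0.97. The smallest falls of KMT5B, TRIM13, NAPEPLD, BLID and ZNF594 lay between -1.33 and -1.74, and ZSWIM3 stayed at or below -2.02. Of 6605 named genes with more than 1 tested probe, 119 had probes past the threshold in both directions, so a value holds for the probe shown.

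Above background on all coculture arrays and no untreated array were 21 named genes, and 63 showed the reverse. The brightest of the first were DEPP1, a FOXO target, at least 2.82-fold higher, MIR93 at least 2.39-fold and CCL20. The brightest of the second were the zinc finger genes ZNF623, at least 4.63-fold lower, and ZSCAN20, at least 4.23-fold, and the bitter taste receptor TAS2R10, at least 4.63-fold. These bounds hold under the main processing only. Across the alternatives the log2 changes of DEPP1, MIR93 and CCL20 shrank to as little as 0.31, 0.25 and 0.25. Those of ZNF623, ZSCAN20 and TAS2R10 shrank to as little as -0.48, -0.50 and -0.59.

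Cell type markers were read beside these groups, since macrophages were on the other side of the membrane. Of 26 macrophage markers with a probe, 11 were above background on all 6 arrays and 13 on none, among them C1QA, LYZ and MRC1. Of the 11 tested, limma called 0 higher and 0 lower (0 adjusted over the list alone), with 3 at an unadjusted p under 0.05. Their median was -0.01, or 0.11 with slide as a block, and camera gave the direction as up with adjusted p = 0.658. Fry, which does not compare with other genes, called these 11 (up, mean change 0.04, beside 0.03 for the median of all features, adjusted p = 0.00121, and 0.0251 in either direction). All 11 markers of MDA-MB-231-like cells were above background on all arrays (1 rose, 0 fell, 1 adjusted over the list alone, median 0.10, or 0.06 with slide as a block, adjusted p = 0.114, and 0.0291 with no filter on dim probes). So were 5 of 8 lymphocyte, 4 of 9 fibroblast and 2 of 6 endothelial markers with a probe. Being above background thus does not by itself show a cell type. Fibroblast markers (5 tested, 1 rose, 1 fell, 2 adjusted over the list alone) had a median of 0.01, or -0.06 with slide as a block, with the camera direction down and adjusted p = 0.890. Lymphocyte markers (6 tested, 1 rose, 0 fell, 1 adjusted over the list alone) had a median of -0.004, or 0.12 with slide as a block, with the camera direction up and adjusted p = 0.840. Only 2 endothelial markers were tested, VWF and PECAM1, at -0.25 and 0.05, too few for a list.

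In total 15 of 26 lists passed, and 11 of 26 with slide as a block, where the contrast rests on untreated replicate 3 alone. With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, while fry called 22 by direction and 25 in either direction. For known lncRNAs the estimated correlation was -0.002, below the preset 0.01, yet camera's adjusted p went from 0.00377 to 0.295. Correlation between genes was thus not what ended that call. Background correction with an offset shrank the changes of dim genes, MIR210HG to 2.53 and KMT5B to -1.42, and the cytokine list median to 0.29. Averaging a gene's probes gave 2.60 for MIR210HG, 0.88 for BCLAF1 and 0.36 for HK2, all still past the threshold. Signs of some small list medians depended on scaling. Quantile normalization turned those of the epithelial and mesenchymal state to -0.04, NRF2 targets to -0.03, MDA-MB-231-like markers to -0.05, fibroblast markers to -0.03, lymphocyte markers to 0.01 and macrophage markers to 0.06. A median shift moves all features up alike, their median from 0.03 to 0.13, so medians near 0 turn by construction: heat shock genes to 0.10, lymphocyte markers to 0.10 and macrophage markers to 0.09.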

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

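All tests of control spots were chosen only after the main result was seen. Control spots for PGK1, a glycolytic enzyme, lie outside the tested features, and 4 of 5 were higher after coculture while no spike-in control passed. The human 3′ and 5′ PGK1 controls rose by 0.489 and 0.522 on the log2 scale (adjusted p = 0.000267 and 0.000251, limma over the bright control probes, n = 3 per group). The mouse and rat 5′ PGK1 controls rose by 0.448 and 0.457 (adjusted p = 0.000397 and 0.000323), and the dim mouse 3′ control read -0.256 and did not pass (adjusted p = 0.368). The human GAPDH controls read 0.19 at the 3′ end and 0.20 at the 5′ end (both adjusted p = 0.142), so both ends read alike. The tested probe of PGK1 itself read -0.14 ± 0.09 and did not pass (adjusted p = 0.323), while 2 of its 3 probes were higher, up to 0.58. The brightest probe stands for a gene here, so the glycolysis list counts PGK1 as not past the threshold.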

How the results depend on the processing

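The random slide effect, the fit within slide 2, the E1A shift, the protein-coding list background and the test of other splits were chosen only after the result was seen. Of the 10 splits of the 6 arrays into 3 and 3, 1 called as many features as the real 14833, namely the real one. The highest other called 0 (limma, up to 2854 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Of 113 genes named by rule, 97 passed, and 67 of these passed in every alternative without a fold limit. NF-kB targets, cytokines, hypoxia, glycolysis and p53 targets passed under every camera alternative at the preset correlation.

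Some counts moved far. Features higher numbered 14501 with a median shift, 4436 with the E1A shift, 5003 with no filter on dim probes (more features tested), 4170 with slide as a block and 3089 within slide 2. Features lower numbered 4598 and 3361 in those slide fits. A fold limit of 2 left 664 higher, 1691 lower and 74 non-coding. Non-coding calls were 1351 with every probe counted, 376 with slide as a block and 278 within slide 2. Leaving out 1 array at a time gave 5095 (without coculture replicate 2) to 8686 (without untreated replicate 3) higher, with fewer arrays in each fit. Without untreated replicate 3 all untreated arrays are on slide 1 and all coculture arrays on slide 2. That fit cannot tell coculture from slide. Lists past the threshold were 7 under quantile normalization, with or without normexp, and 7 with series matrix values. They were 0 with an estimated correlation, 25 with fry's mixed p and 8 against protein-coding genes. Against protein-coding genes the known lncRNAs were not tested, and 6 other lists lost their call. Other causes were not tested.

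Some directions reversed. RPL5 read -0.00414 under normexp with quantile normalization. The oxidative phosphorylation median was -0.0320 there, -0.00248 under quantile normalization and -0.00419 in the series matrix, and ribosomal proteins had medians of 0.00416 and -0.00699 in the first 2, with the camera direction down. The cause of these was not tested. The ZNF median was 0.00798 after a median shift, which moves all features up alike (their median from 0.03 to 0.13), so this turn follows from the shift.

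With the replicate number as a block in a paired fit, 5377 features were higher and 5917 lower. Of the lists, the metallothionein call ended (adjusted p = 0.0646), and 11 named genes no longer passed. Deviations from the group mean correlated between arrays of the same number at -0.01, -0.05 and -0.05 across features.

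Background correction with an offset of 50 shrinks the changes of dim genes by its construction: with the 75th percentile kept, MIR210HG read 2.53, KMT5B -1.42 and ABHD18 -0.60. Signal over background sets the limit for genes dim in 1 group, which are given as bounds.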

Other observations

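The scan of gene families, its family rule, the E1A spike-in shift and the tests of macrophage RNA and of small RNA recovery were chosen only after the result was seen. Genes were grouped by the letters that begin their symbol, after a first scan with a slightly different rule. Of 137 families with at least 12 tested members, camera called 15, and 12 with slide as a block, 9 under quantile normalization and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Box C/D small nucleolar RNAs (SNORD), which guide methylation of ribosomal RNA, rose in 86 of 131 cases and fell in 0, with a median log2 change of 0.42 (adjusted p = 1.11e-17, and adjusted p = 0.921 with an estimated correlation). SNORD35B and SNORD11 rose by 1.53 ± 0.06 and 1.44 ± 0.07. Small Cajal body RNAs (SCARNA) rose in 9 of 21 cases with a median of 0.32, and box H/ACA small nucleolar RNAs (SNORA) in 35 of 96, with 5 lower and a median of 0.16. The adjusted p of both became 0.996 with an estimated correlation. Genes of SR splicing factors (SRSF) rose in 7 of 12 cases, median 0.28, among them SRSF5 at 0.87 ± 0.07 and SRSF6 at 0.68 ± 0.05, with adjusted p = 0.00109, and adjusted p = 0.996 with an estimated correlation. The medians of these 4 families were above 0 under every scaling tried, though that of SNORD shrank to 0.22 with no filter on dim probes and to 0.28 with normexp. The SRSF median shrank to 0.16 under quantile normalization and 0.15 in the series matrix, that of SNORA to 0.10 with normexp and quantile normalization and to 0.10 with the E1A shift, and that of SCARNA to 0.21 with normexp and quantile normalization.

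Zinc finger genes with a ZNF symbol fell in 168 of 453 cases and rose in 73, with a median of -0.10 (adjusted p = 0.000502, and adjusted p = 0.996 with an estimated correlation). That median turned to 0.008 after a median shift, where all features moved up alike, from 0.03 to 0.13. ZSCAN genes, zinc finger genes with a SCAN domain, fell in 11 of 16 cases and rose in 1 (median -0.48, adjusted p = 0.000302), with ZSCAN26 at -0.83 ± 0.05. Bitter taste receptors (TAS2R) fell in 8 of 15 cases and rose in 0 (median -0.24, adjusted p = 0.000302), with TAS2R14 at -0.96 ± 0.06. With an estimated correlation those adjusted p were 0.996 for ZSCAN and 0.921 for TAS2R. The medians of ZSCAN and TAS2R were below 0 under every scaling tried. With no filter on dim probes they shrank to -0.32 and -0.08, and with normexp at the 75th percentile to -0.27 and -0.14, and the TAS2R genes are dim (median signal -0.99).

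For the SNORD genes, probe signal and GC content are argued against as the cause, since their median exceeded that of 10000 random lists matched on both by 0.395 (matched median 0.03, central 95% from -0.02 to 0.07). More mature transcript of the host genes is argued against as the whole cause at the main scaling only. The 50 host genes of 98 SNORD genes had a median of 0.17, which is 0.399 of that of their SNORD genes (bootstrap 95% interval 0.31 to 0.55). Of these hosts 16 were higher and 1 lower. Their changes correlated with those of their SNORD genes at 0.26 (Pearson, permutation p = 0.068). Unspliced transcript of the host genes was not tested. Such a ratio changes with the scaling and was not computed at other settings. There the median of all SNORD genes ran from 0.22 (no filter on dim probes) to 0.53 (median shift), so the question stays open. More small RNA recovered from the coculture samples stays open, as the SNORA median was 0.368 of the SNORD median (0.27 to 0.57) but the SCARNA median 0.754 of it (0.48 to 1.05). A higher level of SNORD RNA in cocultured cells may be the reason, as a hypothesis, and cannot be told apart from a difference in recovery, because the labels give no yield.

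For the ZNF genes, probe signal and GC content are argued against, since the family median differed from that of matched random lists by -0.124, and 0 of 10000 lists were as low. Relative to all tested features the median was -0.142 with slide as a block (bootstrap 95% interval over genes -0.19 to -0.10). This met the bound set beforehand, but that bound was wrong, since only 1 untreated array shares a slide with coculture arrays and the interval leaves out the spread between arrays. A lower level of ZNF mRNA relative to other RNA after coculture may be the reason, as a hypothesis, and cannot be told apart from the slide. An unequal loss of short-lived mRNA between the groups was not tested.

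For the cytokine and chemokine genes, RNA of whole macrophages carried into the coculture samples is argued against as the cause. Of the 13 macrophage markers at background in untreated cells, 0 were above background on any coculture array, among them the abundant C1QA, C1QB, LYZ and TYROBP. Their median change was -0.034 (bootstrap 95% interval -0.10 to 0.02), against 1.02 for the cytokine list. That median reads signal at background, so only the count of markers bears on the question. No macrophage array was at hand to show that these probes detect such RNA, and transfer of selected RNA was not tested. The transwell membrane would also hold back the macrophages themselves. Of 26 macrophage markers with a probe, 11 were above background in untreated cells as well and are no measure of such RNA. Induction of these genes in the cancer cells may account for the rise, as a hypothesis not tested on other samples.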
